A study of Drosophila melanogaster with 4 samples.

How the data were processed

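H3K23ac was profiled by ChIP-seq in head nuclei of adult wild-type Oregon-R flies, in 2 ChIP samples, each with its own input sample. Chromatin was crosslinked with formaldehyde, sonicated and immunoprecipitated, per the labels' protocols. The developmental stage is given as mixed adult, and the proportion of males and females is not stated in the labels. The submitters' processing notes name Bowtie 0.12.7, a short-read aligner. The peak caller, its threshold, read filters and the number of reads are not given in the sources used here. Because the depth is unknown, no interval for read counting was computed.

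The analysed files were 3 lists of regions of significant enrichment, 1 for each ChIP replicate and 1 for the series. Each gives a start, an end and a score for every region. Coordinates are 1-based on FlyBase release 5 of the Drosophila genome, per the file headers, which also give the arm lengths. How the authors combined the replicates in the series list is not given in the sources used here; all starts and ends in it are even numbers, against about 50% in the replicate lists, so it is not a plain union of them. Its values are the authors' own and carry no SD or n.

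The score of each deposited region is on a log2 scale, as read from the values, since no header or label names its unit. For 100% of the regions of both replicates and 99.6% of the combined list, 2 to the power of the difference between a score and the most frequent score of its list was a ratio of whole numbers (relative tolerance 1e-12, denominators up to 20000). Of random scores, 0.2% met this test. The score therefore behaves as the log2 of a ratio of counts times 1 constant for each list. The constant, and so the zero point, is not known, and levels of scores were not compared between the replicate and combined lists. Each ratio was multiplied by 1 factor for its list, a ratio of small whole numbers chosen to make numerators and denominators smallest. The geometric mean of the numerator and denominator of the result in lowest terms was used as a count index. It is a rough relative measure of the reads behind a score and not a read count: common factors cancel in the ratio, which makes it noisy, and it varies with the level of the score. For X, it was also compared with autosomal regions weighted to the same scores in bins of 0.05.

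Covered lengths, shift tests and comparisons between chromosomes used arms 2L, 2R, 3L, 3R and X and chromosome 4, 120.382 Mb in all. Autosomes here means 2L, 2R, 3L and 3R. Windows of 1 Mb were taken on 2L, 2R, 3L, 3R and X only. Counts, widths and scores of whole lists include the few regions on heterochromatin scaffolds and unplaced scaffolds. So do the split into shared and single regions and the comparison of the combined list with the replicates. Regions on these scaffolds were also counted separately. The replicate lists were compared by the share of regions overlapping by at least 1 bp and by the Jaccard index of covered length. The one-sided permutation test shifted the list of replicate 2 circularly within each arm by a random offset, 1000 times. For shares, it counted the regions of replicate 2 only. Separate sets of 1000 shifts were drawn for single arms, for the widths of shared regions and for broad regions, after the data were seen. Scores were compared across all pairs of overlapping regions with Spearman and Pearson coefficients and no p-value, since regions are not independent replicates. Intervals for ratios between chromosomes were drawn by resampling windows of 1 Mb, 10000 times, and describe variation along the genome, not between animals. The interval for the score correlation was drawn by resampling pairs of regions, 1000 times. It treats pairs as independent and does not describe variation between animals either. Shares of combined regions carry exact binomial (Clopper-Pearson) 95% intervals. Values per replicate are given as mean ± SD, n = 2. Arm ends were taken as the outer 2 Mb, broad regions as those of at least 10 kb, and the count index was compared per kb over regions of 1301 to 2000 bp. The clustering of regions was compared with 1000 random orders of the same regions and gaps within each arm, in windows of 100 kb.

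The designs, the main alternatives and the rule for named regions were fixed before the data were examined. The rule took the 10 widest and the 10 highest-scoring regions of the combined list, by position where no annotation of the same build was used. The gene table used with this series belongs to release 6 of the genome and the files to release 5, and coordinates were not converted. Start sites, gene features, gene bodies and the 22 gene lists fixed beforehand were therefore not tested, and no gene is named. The alternatives were a reciprocal overlap of 50%, regions above the median score of their list, merging of regions less than 1000 bp apart, removal of regions under 500 bp, leaving out X or a replicate, and use of the combined list in place of the replicates. Others were added after the data were seen, among them shifts within the marked span of each arm and a minimum length for combined regions.

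Calculations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The procedures were tested on simulated data. The shift test gave a p under 0.05 in 0 of 20 simulated pairs of independent lists and in 5 of 5 pairs that shared 60% of regions. The random-order test gave a p under 0.05 in 0 of 20 lists simulated in random order. Simulated regions were placed at random on 2L, 2R, 3L, 3R and X, without the clustering and empty arm ends of the real lists. Fewer than 1000 shifts or orders were drawn for them. The simulations therefore do not give the error rate of the shift test for lists like the real ones. Overlaps of 1000 regions matched a brute-force count with 0 differences. When simulated counts were reduced to 75% and 50%, the count index fell to 0.774 and 0.474 of its value. Full and reduced counts had like scores and shared 1 list factor. X and autosomal regions differ in score, and the combined and replicate lists had separate factors. The simulation does not show how the index behaves there.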

Results

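H3K23ac, the acetylation of lysine 23 on histone H3, is a mark of open, transcribed chromatin. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from the heads of adult Drosophila melanogaster of the wild-type Oregon-R strain. The series held 4 samples, namely 2 ChIP samples and 2 inputs, the unenriched chromatin that served as the background for each ChIP sample. A list of enriched regions was analysed for ChIP replicate 1, another for ChIP replicate 2, and a combined list for the whole series; no file of the input samples was used here. The labels do not say whether the replicates came from separate collections of flies, so the spread between them may be technical. Read numbers are not given in the sources used here, and the depth of each sample is unknown.

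H3K23ac regions covered about the same share of the genome in both replicates. Replicate 1 had 9467 regions and replicate 2 had 9142, each with 1 region on an unplaced scaffold. The others covered 24.5 Mb in replicate 1 and 24.0 Mb in replicate 2. This was 20.2% ± 0.315 (SD, n = 2) of the 120.382 Mb of chromosome arms 2L, 2R, 3L, 3R and X and chromosome 4. Regions were short domains: the median width was 1927 bp in replicate 1 and 1935 bp in replicate 2, the shortest region was 1301 bp in both, and the widest were 41780 bp and 55751 bp. The median gap between neighbouring regions was 3395.5 bp in replicate 1 and 3336 bp in replicate 2. Wider regions had higher scores within each list (Spearman rho 0.49 and 0.50 across regions, which are not independent replicates).

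The first comparison asked how far the replicates marked the same places. Of the regions of replicate 1, 67.5% overlapped a region of replicate 2 by at least 1 bp, and 69.7% of the regions of replicate 2 overlapped one of replicate 1. The replicates shared 15.2 Mb of the 33.3 Mb covered in either, a Jaccard index of 0.456. The index was 0.520 on 2R, 0.469 on 3R, 0.466 on 3L, 0.447 on 2L, 0.306 on X and 0.263 on chromosome 4. The means of 1000 shifted lists of the same arm were 0.156, 0.134, 0.112, 0.102, 0.0639 and 0.0123. Both the index and its ratio to shifted lists depend on the share covered, so the arms were not ranked. Regions found in both lists were wider than those found in one: in replicate 1 the medians were 2183 bp over 6388 shared regions and 1571 bp over 3079 others, and in replicate 2 they were 2170 bp over 6375 and 1566 bp over 2767. Wide regions also meet another list more often by chance: the differences of medians were 612 bp and 604 bp, against 197 bp ± 22.9 and 207 bp ± 23.9 in shifted lists (SD over 1000 shifts). When the list of replicate 2 was shifted along each arm at random, 35.9% ± 0.771 of its regions overlapped replicate 1 (SD over 1000 shifts). The Jaccard index of the shifted lists was at most 0.148. The observed index was 3.79 times the mean of the shifted lists. The permutation p, one-sided, was 0.001 for both the share of replicate 2 regions and the Jaccard index. This is the smallest that 1000 shifts can give. When the overlap had to span at least 50% of both regions, the share of overlapping regions, pooled over both lists, fell from 68.6% to 43.5%. In shifted lists 10.6% of the replicate 2 regions met this rule, which is not a pooled share.

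Over long windows the replicates were covered nearly alike. Across the 117 full windows of 1 Mb, the covered share in the replicates had a Pearson r of 0.98 and a Spearman rho of 0.98; windows are not independent replicates. The median difference between replicates in a window was 1.26 percentage points and the largest was 5.09. The scores of overlapping regions were less closely related, with a Spearman rho of 0.47 and a Pearson r of 0.50 across 7460 pairs. The 95% bootstrap interval of rho, over pairs of regions, was 0.446 to 0.485. Neighbouring pairs are not independent, so the interval may be too narrow. Among the 4048 pairs that overlapped by at least 50% of both regions, rho was 0.61. It was lower than the pooled value both without X, at 0.39 over 6674 pairs, and within X, at 0.35 over 786 pairs.

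The next comparison asked how H3K23ac was spread over the chromosomes. Arm 2R was the most densely covered, at 26.9% ± 0.322 (SD, n = 2 here and below), followed by 3R at 23.6% ± 0.203, 3L at 20.3% ± 0.297 and 2L at 18.4% ± 0.318. The X chromosome had 12.1% ± 1.15 covered, against 22.3% ± 0.129 over the autosomal arms 2L, 2R, 3L and 3R together. The small chromosome 4, which is largely heterochromatic, had 2.41% ± 0.182 covered, by 15 regions in replicate 1 and 20 in replicate 2. X carried 55.6 ± 4.64 regions per Mb, the autosomal arms 83.2 ± 1.34 and chromosome 4 12.9 ± 2.62.

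The ratio of the covered share of X to that of the autosomal arms was 0.579 in replicate 1 (95% bootstrap interval over windows of 1 Mb, 0.456 to 0.727) and 0.511 in replicate 2 (0.394 to 0.652), with a mean of 0.545 ± 0.0485. The differences of X and of chromosome 4 from the autosomal arms were larger than the spread between replicates, but the signs of 2 within-replicate differences cannot give a two-sided exact p below 0.5. The ratio rose to 0.828 when only regions with scores above the list median were kept. Chromosome 4 was at 0.108 ± 0.00879 of the autosomal share, and at 0.0343 under the same stricter threshold. In the combined list X had 34.6% covered, the autosomal arms 45.9% and chromosome 4 6.90%.

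**Figure D1:**
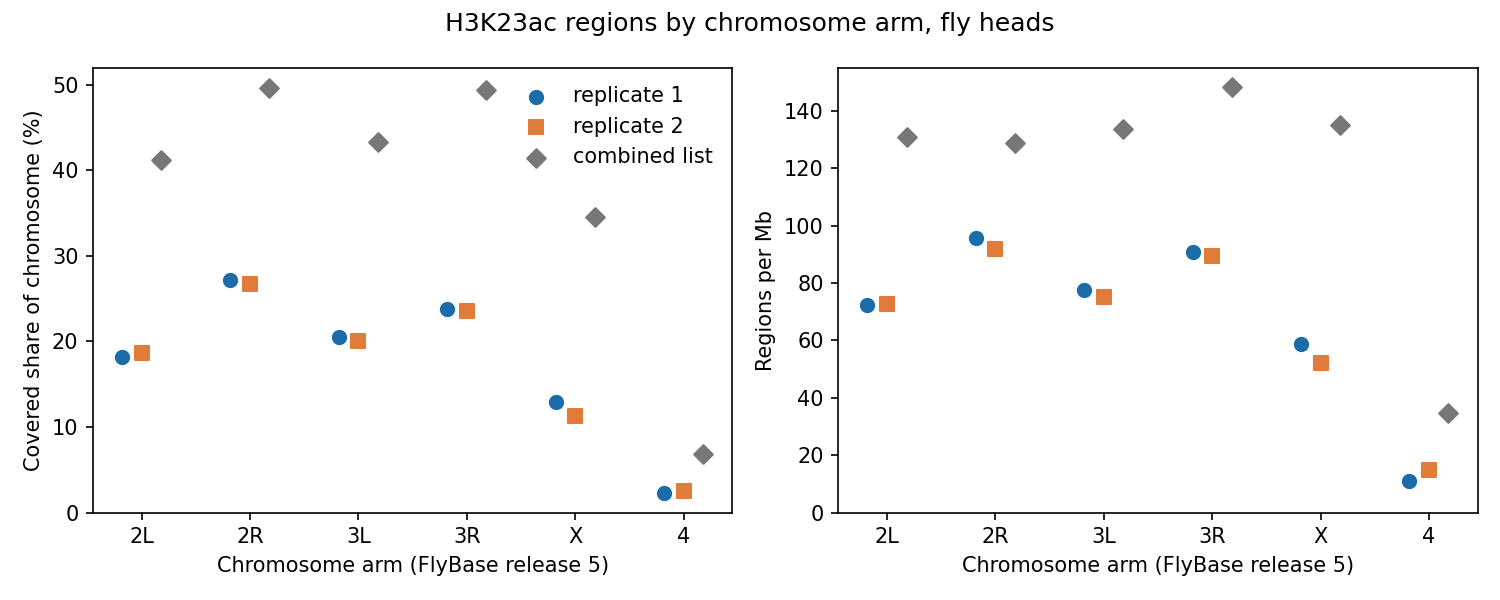
H3K23ac regions on each chromosome arm in replicate 1, replicate 2 and the combined list; each point is 1 list. The left panel gives the share of the arm covered in percent and the right panel the number of regions per Mb. In the replicates X lies at 12.9% and 11.3%, below the arms 2L, 2R, 3L and 3R, and chromosome 4 lies lowest at 2.28% and 2.54%.

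Although X had fewer regions, those it had scored higher. The median score of X regions was 0.71 in replicate 1 and 0.70 in replicate 2, against 0.57 over the autosomal arms in both. The difference on the log2 scale of the authors' score was 0.14 ± 0.0073 (SD, n = 2), a 1.10-fold difference. The 4 autosomal arms lay together, with medians from 0.56 to 0.58 in each replicate. The low end of the scores was also higher on X, with a 10th percentile of 0.570 in replicate 1 and 0.573 in replicate 2. On the autosomal arms it was 0.443 to 0.457 in replicate 1 and 0.448 to 0.466 in replicate 2. These values cover called regions only, and whether the threshold differed on X is not known. X held 13.9% of the regions of replicate 1 but 38.6% of those in the upper 25% of scores, and 12.8% and 34.8% in replicate 2. Regions in this upper 25% numbered 40.8 per Mb on X and 15.0 per Mb on the autosomal arms in replicate 1, and 35.5 and 15.4 per Mb in replicate 2. X regions were slightly narrower, with median widths of 1768.5 bp and 1751 bp against 1956 bp and 1967 bp. A count index, a rough relative measure of the reads behind a score, was per kb of region 0.606 and 0.626 of the autosomal value on X in replicates 1 and 2. The index also varies with the score: against autosomal regions matched to X by score, a comparison added after the data were seen, it was 0.839 and 0.764.

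**Figure D2:**
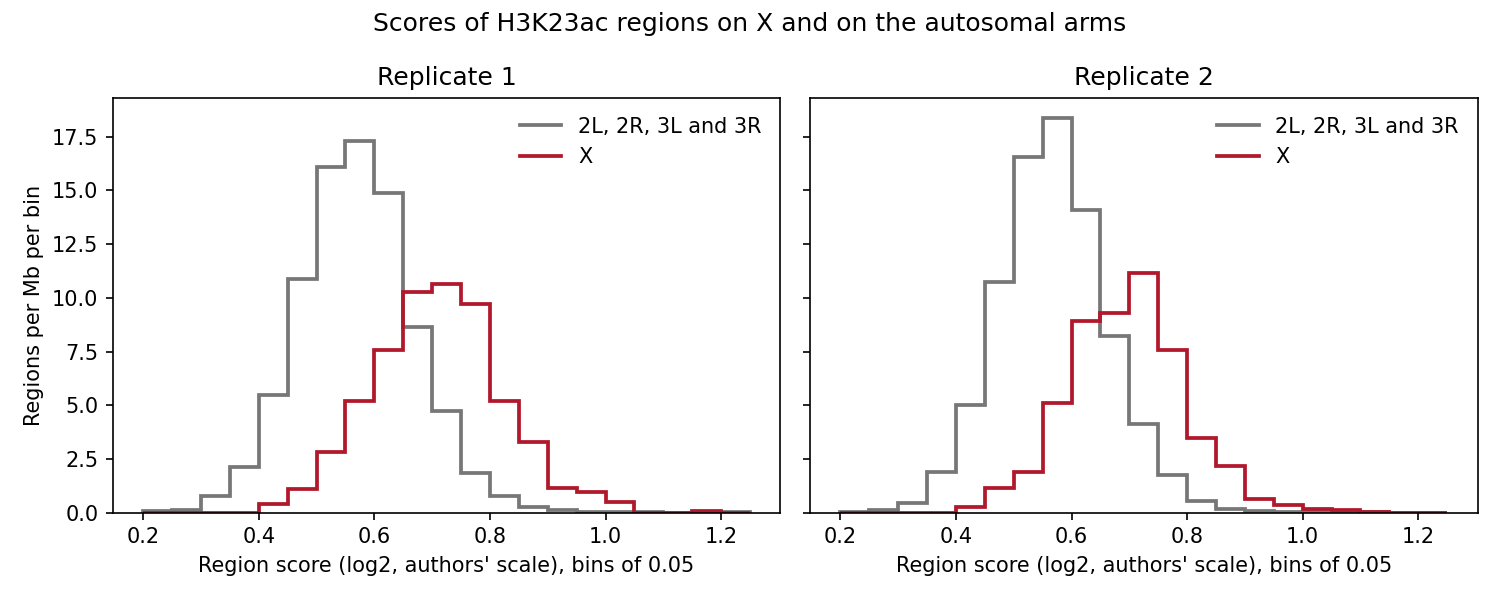
Scores of H3K23ac regions on X and on the autosomal arms 2L, 2R, 3L and 3R in each replicate. The horizontal axis is the authors' region score on a log2 scale in bins of 0.05 and the vertical axis is regions per Mb in each bin. The X distribution is shifted to higher scores in both replicates, with medians of 0.71 and 0.70 against 0.57 and 0.57.

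Along each arm, the telomere side was more covered than the centromere side. In the 2 Mb at each end, coverage on the telomere side was 30.6% ± 1.70 on 2L, 31.7% ± 0.0130 on 2R, 36.6% ± 0.654 on 3L, 36.2% ± 1.66 on 3R and 28.3% ± 2.30 on X. On the centromere side it was 4.80% ± 0.0461 on 2L, 8.39% ± 0.0223 on 2R, 7.03% ± 0.554 on 3L and 4.95% ± 0.719 on X. Arm 3R differed, with 28.6% ± 0.221 in its first 2 Mb, above its middle at 22.2% ± 0.394. On X the telomere side was 28.3% covered and the middle of the arm 11.2% ± 1.07. The first region of 2R started at 1.57 Mb in each of the 3 lists, and no region lay in the last 1.54 Mb of 3L.

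The most covered full 1-Mb windows were 3L from 22 to 23 Mb, at 43.4% and 46.1% in replicates 1 and 2, 2R from 20 to 21 Mb, at 43.1% and 44.8%, and 3L from 0 to 1 Mb, at 41.2% and 43.0%. The window on 3L at 22 to 23 Mb adjoined the unmarked centromere side of the arm. Of the full windows, 3 were less than 1% covered in both replicates, each on the centromere side of its arm: 2L from 22 to 23 Mb, 2R from 0 to 1 Mb and 3L from 23 to 24 Mb. The least covered windows away from the arm ends were 2L from 15 to 16 Mb, at 3.16% and 4.17%, 2L from 17 to 18 Mb, at 4.95% and 5.05%, and X from 15 to 16 Mb, at 6.54% and 3.66%.

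**Figure D3:**
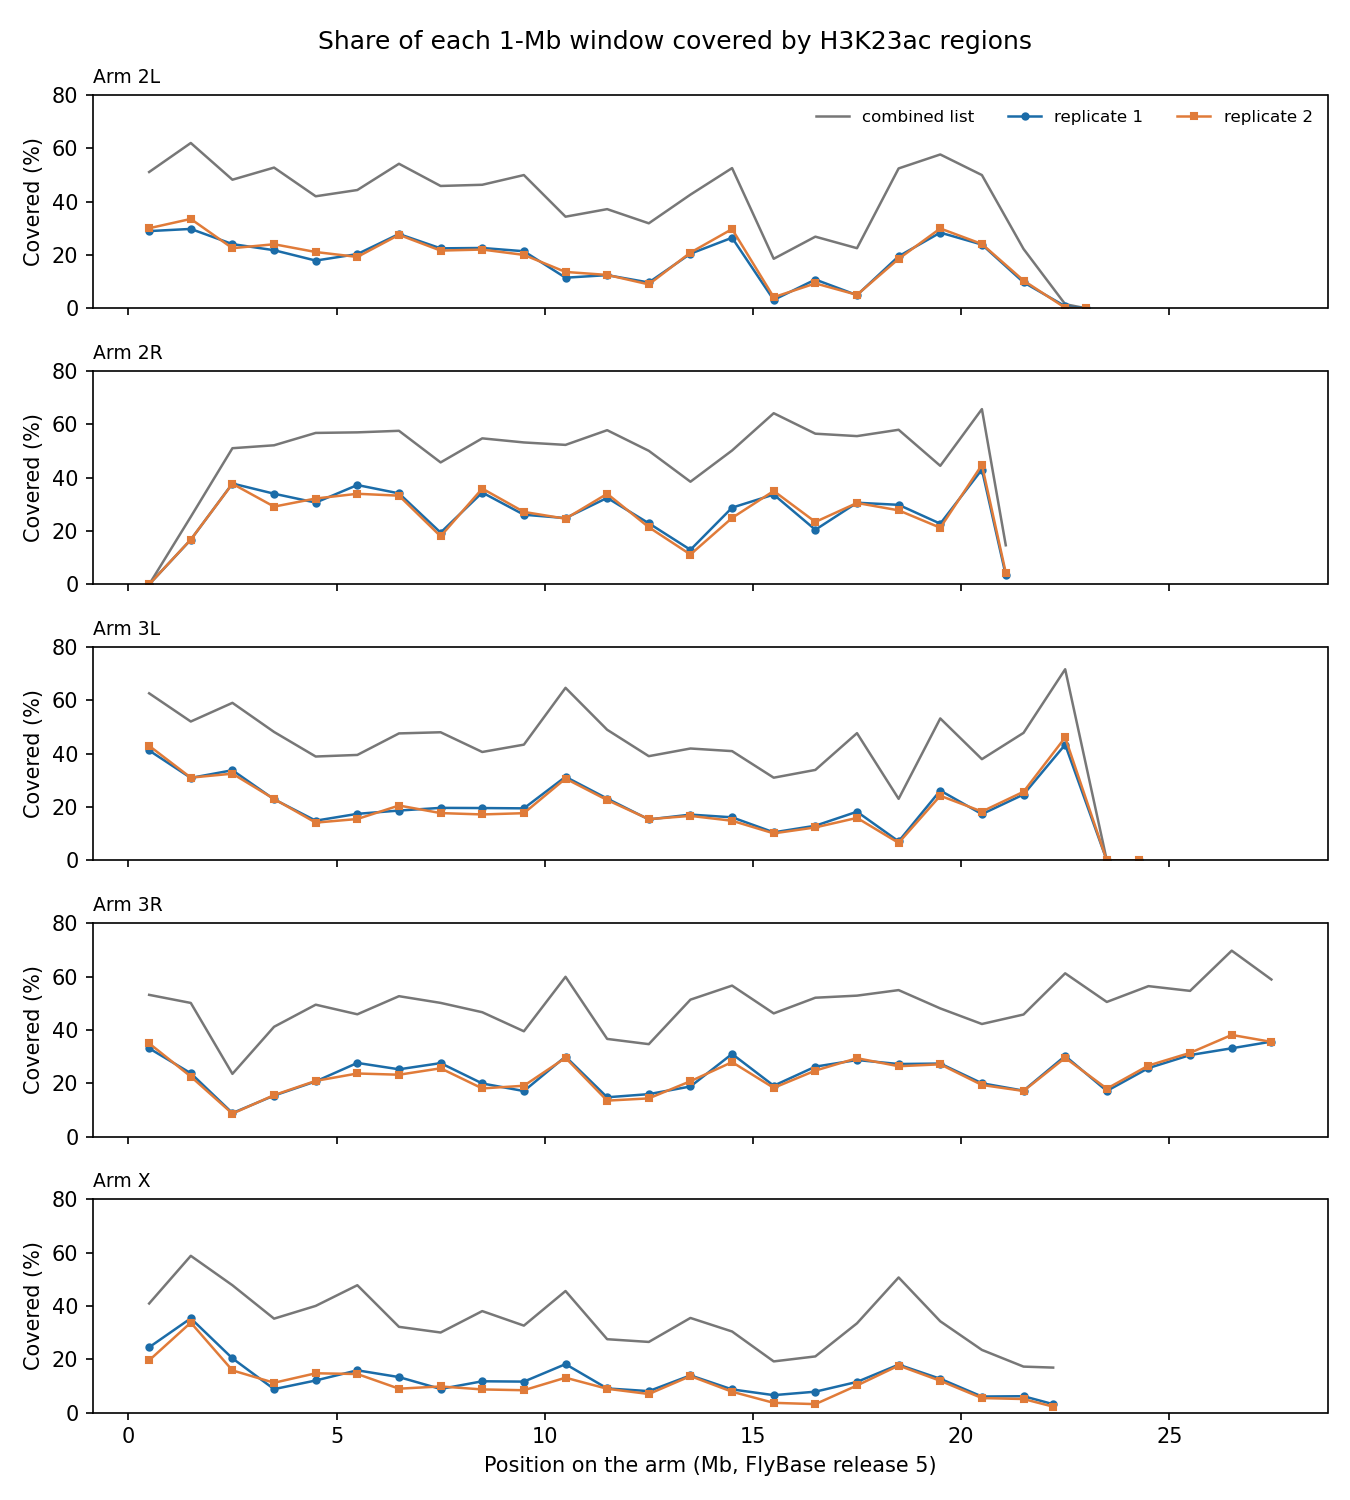
Share of each 1-Mb window covered by H3K23ac regions along arms 2L, 2R, 3L, 3R and X, for replicate 1, replicate 2 and the combined list. The horizontal axis is the position in Mb on FlyBase release 5 and the vertical axis the covered share in percent; the last window of an arm can be shorter than 1 Mb. The replicates follow each other closely, with a largest difference of 5.09 percentage points in a full window.

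The last comparison set the combined list against the replicates. The combined list had 16244 regions, of which 9 on scaffold U, 3 on XHet and 1 on 3LHet lay outside the arms and chromosome 4. On the arms and chromosome 4 it covered 52.2 Mb, 43.4% of the sequence. This was 2.13 times the length of replicate 1 and 2.18 times that of replicate 2. The combined list took in nearly all of the replicate lists: 99.6% of the regions of each replicate overlapped it, all but 34 and 35 regions. Of the combined regions, 27.9% overlapped both replicate lists (exact binomial 95% interval 27.2 to 28.6), 14.8% replicate 1 only, 12.9% replicate 2 only and 44.4% neither (43.7 to 45.2). The intervals cover counting over regions only. The regions found in both replicates were wide, with a median of 4879 bp, and made up 57.8% of the combined length. Those in neither had a median of 1353 bp and made up 21.1%. Wide regions also meet other lists more often by chance, and no shifted lists were drawn for this comparison. On X 51.7% of combined regions were in neither replicate, against 42.7% on the autosomal arms. The share in both fell to 16.8% when each list had to cover at least 50% of the combined region. The number of regions per Mb in the combined list was 135 on X and 136 on the autosomal arms, 2.43 and 1.64 times the mean of the replicates.

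The 10 widest regions of the combined list were covered in each replicate over at least 72.6% of their length. The combined list stands for the same series and took in nearly all regions of both replicates, so this is not independent support. The widest was 105589 bp on 3L (22295546 to 22401134, FlyBase release 5, as are all positions here), with a score of 0.73, of which 94.9% was covered in replicate 1 and 95.2% in replicate 2. It was followed by 72861 bp on 2R (2389474 to 2462334), covered over 96.6% and 93.5%, and 56567 bp on 3L (770068 to 826634), covered over 94.2% and 98.6% and with the highest score of the 10, 0.93. The region on 2R began where an unmarked stretch of 249591 bp ended. The next were 2R 17308952 to 17363648, 3R 5700666 to 5754122, 3L 5188250 to 5240966 and 3L 1102536 to 1154576, between 54697 bp and 52041 bp wide. The remainder were 3L 13222016 to 13271752, 2R 4685824 to 4732174 and 3R 19432488 to 19478508, between 49737 bp and 46021 bp. None of the 10 lay on X.

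The 10 highest-scoring regions of the combined list overlapped no region of either replicate. They were 1001 to 1007 bp wide, with scores from 2.26 to 3.30, and were led by 3R 4236980 to 4237986 at 3.30. At 3.06 came 3L 16437002 to 16438004, 3L 7881120 to 7882120, 3L 9930522 to 9931522 and X 5421536 to 5422536. The others were 2R 16256066 to 16257066 and X 3309082 to 3310082 at 2.92, 3R 6082438 to 6083438 and 3R 25232434 to 25233434 at 2.41, and X 6328016 to 6329018 at 2.26. Of the 27 combined regions with a score of at least 1, 25 lay outside both replicate lists. The median count index of these 25 was 3.61, against 162 over 1531 other combined regions of at most 1100 bp, which could not be matched to them by score. The other 2 of the 27 were found in both replicates and were singled out after their values were seen: X 2020266 to 2026784, 6519 bp wide with a score of 1.07, and 2R 8843756 to 8868336, 24581 bp wide with a score of 1.00. In the replicate lists the highest scores within the X region were 1.16 and 1.08, and within the 2R region 1.08 and 1.04. Each list has its own unknown zero point, so these levels are not compared with the combined scores.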

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

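The combined list held 9 regions on scaffold U, the sequence not placed on any chromosome, which the comparisons between arms leave out. They are given here as signal in sequence that no comparison between chromosomes uses. They do count among the regions of the combined list set against the replicates. No list of a control sample was used to set them against. Each replicate had 1 region there, at the same place: 5631232 to 5633169 in replicate 1 and 5631200 to 5633498 in replicate 2, with a combined region at 5631194 to 5633546. The other combined regions on U were in neither replicate. The combined list also had 3 regions on the heterochromatin scaffold XHet and 1 on 3LHet, while 2LHet, 2RHet, 3RHet, YHet and Uextra had 0 in each list. Scaffold U holds 10.0 Mb, of which the combined regions covered 0.143%. No explanation was tested.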

How the results depend on the processing

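Alternatives chosen after the data were seen are the shift within the marked span of each arm, the span-limited and within-chromosome versions of the covered share, the length minimum for combined regions and those of the X score difference and count index. Of the values under alternatives, 13 moved by more than the spread and 0 reversed, but no alternative used a score cut above the median. The other 23 kept their direction and their side of the threshold or moved by less than the spread, but some of these show nothing: 8 leave out 1 of 2 replicates, which cannot move a mean by more than the SD, and 2 remove regions under 500 bp, of which there were none. Over the alternatives run, the pooled share of overlapping regions ranged from 43.5% to 68.6% and the Jaccard index from 0.386 to 0.473. The permutation p, taken for shares on replicate 2 regions, was always 0.001, the smallest 1000 shifts can give. The score correlation of 0.47 became 0.61 with a reciprocal overlap of 50% and 0.39 with X left out.

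The share of combined regions in both replicates, 27.9%, was 16.8% with at least 50% of the region covered, 25.7% among regions above the median score, and 35.5% among regions at least as long as the shortest in the replicates. With a single replicate required it was 40.8% to 42.7%, as fewer lists have to overlap. The X to autosome ratio of covered shares, 0.545, was 0.828 above the median score and 0.753 in the combined list, but 0.499 when the median was taken within X and within the rest, so the rise came from the higher scores of X. For chromosome 4 the ratio of 0.108 became 0.0343 above the median score and 0.150 in the combined list. The X score difference of 0.135 became 0.0929 in the combined list. The count index ratio of X, 0.616, became 0.802 against autosomal regions matched by score, so part of it followed the score. Unless stated, the cause was not tested.

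No paired analysis was possible because no file of the input samples was used here. Overlap of the replicates cannot be computed with a replicate left out. The alternatives of all gene-level results were not run, as those results were not. Unknown depth limits every list: a place outside a list was not called there, which does not show that it lacks the mark.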

Other observations

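Tests chosen after the result was seen were the coverage of X without its ends, the score-matched count index of X, the count index of the highest-scoring regions and that of the combined list; the unmatched count index of X, the shortest length and the random order were chosen after the data, but before their own results, were seen. The shifted lists for broad regions were also added after the data were seen, and the unmarked stretches were described without a test.

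Broad H3K23ac regions of at least 10 kb numbered 122 in replicate 1 and 146 in replicate 2, and made up 7.12% and 8.57% of the covered length. They were densest on 2R, with 15.6 and 22.2 per 10 Mb, and on 3R, with 14.0 in both. X had 2.68 and 2.23 per 10 Mb and chromosome 4 had 0. Their median scores were 0.73 and 0.72, against 0.58 over other regions in both lists. In the other replicate 98.4% and 100% of them were at least 50% covered, against 15.8% ± 3.95 and 15.8% ± 3.57 in shifted lists (SD over 1000 shifts). Fewer, 53.3% and 45.2%, overlapped a region that was itself broad in the other list, against 3.94% ± 2.29 and 3.33% ± 1.85 in shifted lists.

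Long unmarked stretches were also found. On arms 2L, 2R, 3L, 3R and X, the combined list left 45 stretches of at least 50 kb between neighbouring regions. Of these, 15 were on 2L, 14 on X, 7 on 3L, 5 on 3R and 4 on 2R. The longest was 368785 bp on X (21490293 to 21859077), followed by 262295 bp on 2L (21387651 to 21649945), both without a base covered in either replicate. Next were 249591 bp on 2R (2139883 to 2389473) and 152553 bp on 2L (10196915 to 10349467); replicate 1 covered 102 bp of the 2R stretch. Whether reads could not be placed there or the mark was absent was not tested, since mappability was not analysed here.

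Coverage was more uneven along the arms than the same regions and gaps in random order would give. The SD of the covered share over windows of 100 kb was 15.9 points in replicate 1 and 16.2 in replicate 2, on average 1.34 times that of the same regions and gaps in random order (11.8 ± 0.151 and 12.0 ± 0.150, SD over 1000 orders). The permutation p, one-sided, was 0.001 in each replicate, the smallest 1000 orders can give. Random order alone is therefore argued against. Positions of genes of the same build were not used, so no relation to genes was tested.

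H3K23ac regions covered less of X than of the autosomal arms. The sparsely covered centromere-side end of X is argued against as the cause, since the ratio of covered shares was 0.504 without the 2 Mb at each end of every arm. Fewer reads over X remain open: the count index per kb on X was 0.616 of the autosomal value as the mean of the replicates and 0.802 of it after matching by score, while single autosomal arms lay between 0.985 and 1.02 unmatched. With fewer reads weakly enriched places may miss the threshold. In the combined list the ratio of covered shares was 0.753, with 135 regions per Mb on X and 136 on the autosomal arms. How that list was made is not known, so these values do not decide the question. Whether fewer reads also raise the scores on X was not tested. The sexes in the sample are not stated, and a difference of the mark itself on X, such as one tied to dosage compensation, also stays open and untested.

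Of the 27 combined regions with a score of at least 1, 25 lay outside both replicate lists. The median count index of these 25 was 0.0223 times that of other combined regions of at most 1100 bp, with no match by score, so a high ratio over few reads is a candidate explanation. The shortest region in the replicate lists, 1301 bp, could also keep them out, but 7.28% of the 3487 shorter combined regions did overlap a replicate region, between the bounds set for and against it, so its part cannot be told apart from that of few reads. No biological explanation was tested.

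Many combined regions lay outside both replicate lists. The count index per kb of combined regions of 1301 to 2000 bp was on average 1.75 times that of the replicate lists (1.75 and 1.76), which is consistent with more reads behind the combined list letting weaker regions pass. The index is not a read count and varies with the score, which could not be matched between these lists. Its factor was also chosen for each list separately. How the list was made is not given in the sources used here. Of the combined regions, 3487 were shorter than any replicate region, and 7.28% of these overlapped a replicate region. The part of this length limit was not separated from that of more reads. No biological explanation was tested.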
